A study of Homo sapiens with 6 samples.

How the data were processed

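Bulk RNA-seq was analysed for 6 libraries of SC1, a human B-cell lymphoma line, 3 treated with bryostatin at 1 nM and 3 with DMSO. Per the labels, RNA with an integrity number over 7 was enriched for poly(A) tails with oligo(dT) beads, copied from random primers and read as paired ends on a DNA nanoball platform. Selection for poly(A) leaves out transcripts without tails, such as most replication-dependent histone transcripts, and random priming of fragments gives long transcripts more counts than short ones at the same molar level.

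The authors deposited 1 table with expected counts, FPKM and TPM for each library. Expected counts are estimates in which reads that match several transcripts are shared among them, and 6.31 to 7.22% of the deposited values in a library were not whole numbers. FPKM values, deposited by the authors beside them, divide by transcript length and library size, and the TPM values, also deposited, are scaled to 1000000 per library. HISAT2 2.2.1, RSEM 1.2.28, DESeq2 1.40.2 and the build GRCh38 are named in the submitters' processing notes, with no role or order. The annotation and the use of strand were not given in the sources used here, so genes with near-identical copies or overlapping neighbours are uncertain. Genes carried Entrez identifiers and symbols, and 15767 of 15802 identifiers matched the RefSeq gene table of GRCh38.p14, from which the coordinates come (1-based). None of the 13 mitochondrially encoded genes was in the table analysed here, so their planned share of counts is not given.

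Depth was 18162161 to 18915394 expected counts per library, with little difference between the groups. Counts were simulated independently for each gene from the DMSO means, the real library sizes and the fitted spread. On them the 3 against 3 test recovered 58.2% of 67 genes changed 1.5-fold, 82.1% of 67 changed 2-fold and 98.4% of 64 changed 4-fold. These were among 11466 genes, and 0.151% of unchanged genes was called. A simulated shifted list was found and 0 of 28 random lists was called. Because the simulated genes were independent, this cannot show how often camera calls lists of correlated genes. The 2 against 3 test without bryostatin 1 recovered 77.6, 86.6 and 95.4% among 11628 genes and called 0.140% of unchanged genes. The spread of a gene was the same in all simulated libraries, while in the data bryostatin 1 stood apart. These shares are therefore not the power of the test on the real libraries. No pair of libraries was a duplicate, with a chi-square per gene of 2.73 to 4.37 between DMSO libraries, 2.91 between bryostatin 2 and 3, and 40.9 and 37.4 between bryostatin 1 and those libraries.

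Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, robust quasi-likelihood fit, 2-sided, Benjamini-Hochberg over 11613 genes, threshold 0.05). The TMM factor was 0.952 for bryostatin 1 and 1.00 to 1.02 for the others. The SE of a log2 fold change was taken as its size divided by the root of the F statistic. CPM were computed from the rounded counts with the TMM factors. Gene lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01, Benjamini-Hochberg over 29 lists). It called 15 lists, 13 up and 2 down. With the correlation estimated from these few libraries it called 0, with 9 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0699. The rotation test fry, which asks whether a list's genes move one way without reference to other genes, called 17. The share of counts in the 10 most abundant genes was compared by an exact permutation test over 10 splits.

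The groups, the comparison, the 30 lists, the rule for named genes and most of the alternative settings were fixed before the data were examined. The lists covered PKC and PKD, diacylglycerol and MAPK signalling, immediate-early and ERK output, NF-kB targets, B-cell surface antigens, B-cell receptor signalling, germinal centre, plasma cell, B-cell identity factors, activation, MHC class I and II, interferon-stimulated genes, migration, cytokines, BCL2 family, p53 and CDK inhibitors, S phase, G2 and M phase, ribosome biogenesis, cholesterol, glycolysis, unfolded protein response, autophagy and lysosome, T and NK, myeloid and epithelial, stromal or endothelial markers, mitochondrially encoded genes, histones and ribosomal proteins. Some genes stand on several lists. Named genes were the 8 highest and 8 lowest log2 fold changes among genes with an adjusted p under 0.05, at least 10 CPM on average and separated libraries; the 2 members of each list with the smallest p (4 for PKC, surface antigens, BCL2 family and NF-kB targets); and 14 genes always given. This rule named 81 genes, of which 54 passed. Genes outside it are marked as chosen after their values were seen. Of the 81, 1 is not reported here.

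The alternatives fixed in advance were RLE, upper quartile or no scaling factors, no filter or a mean count of at least 10, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1), the replicate number as a block, and each library left out. After bryostatin 1 was seen to stand apart, limma-voom with library quality weights and an offset per gene and library were added. The offset came from natural splines (4 degrees of freedom) on the length and GC content of the longest protein-coding transcript, which 99.6% of tested genes had. Further lists, of which 2 are given in the closing section, were also written after the data were seen.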

Results

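RNA was measured by bulk sequencing in SC1, a human B-cell lymphoma line, after treatment with bryostatin at 1 nM or with DMSO, the solvent control. Bryostatin is a macrocyclic lactone that binds the diacylglycerol-binding domain of protein kinase C (PKC) and modulates its activity. Each group held 3 libraries, named here bryostatin 1 to 3 and DMSO 1 to 3, and the duration of treatment was not given in the sources used here. The deposited gene table held expected counts for 15802 genes. Total expected counts were 18377934, 18458633 and 18162161 in bryostatin 1, 2 and 3 and 18915394, 18574860 and 18545489 in DMSO 1, 2 and 3, and 13930 to 14357 genes had a value over 0 in a library. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. CPM (counts per 1000000 counts of the scaled library size) are given as mean ± SD with n = 3 libraries in each group, and log2 fold changes (bryostatin over DMSO) as estimate ± SE.

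The comparison of bryostatin with DMSO asked which transcripts differ in these lymphoma cells after exposure to the PKC ligand. Several B-cell surface and signalling transcripts were higher with bryostatin. CD180, a Toll-like receptor homologue of B cells, rose 8.99-fold from 8.65 ± 0.391 to 77.9 ± 3.79 CPM. The SHP-1 phosphatase gene PTPN6 rose 7.55-fold, the sialic acid-binding co-receptor CD22 rose 3.45-fold, and the lymphotoxin gene LTB rose 6.70-fold. Of the plasma-cell differentiation transcripts, 6 fell, among them PRDM1 and IRF4. In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 529 of 11613 genes tested changed, 432 higher and 97 lower, and 2176 genes had an unadjusted p under 0.05. Of the 529, 146 changed over 2-fold, 136 higher and 10 lower. All 529 had every bryostatin library on one side of every DMSO library, which passing the test with so few libraries nearly requires. Of all tested genes 27.8% had this, against 10% by chance. The median log2 fold change of all tested genes was 0.00 (-0.00139), and with library size as the only scaling the calls were 379 higher and 138 lower. The TPM values gave 266 higher and 195 lower, with a median of all genes of -0.08. Bryostatin 1 stood apart from its group, and without it 1632 genes rose and 1551 fell, the 529 among them with the same direction. Without bryostatin 2, bryostatin 3, DMSO 1, DMSO 2 and DMSO 3 the number changed was 332, 279, 138, 160 and 145. The length and GC offset gave 782 higher and 440 lower, and library quality weights gave 1609 and 1431.

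Among genes that passed with at least 10 CPM and met the naming rule, the largest rises were those of HTR3A, CD180, HVCN1, PTPN6, MOB3A, LTB, LAT2 and LYL1. HTR3A, a subunit of a serotonin-gated ion channel, rose by 3.82 ± 0.16 on the log2 scale (48.2 ± 7.26 against 3.39 ± 0.553 CPM, edgeR adjusted p = 2.36e-05). HVCN1, a voltage-gated proton channel, rose 7.98-fold (37.4 ± 3.15 against 4.68 ± 0.329 CPM, adjusted p = 9.58e-06). MOB3A, a MOB-family protein, reached 79.0 ± 14.1 against 11.7 ± 0.727 CPM (adjusted p = 8.54e-05). The membrane adaptor LAT2 reached 110 ± 3.73 against 25 ± 1.19 CPM (adjusted p = 9.41e-06) and the basic helix-loop-helix factor LYL1 23.3 ± 2.66 against 5.27 ± 0.605 CPM (adjusted p = 1.63e-04). The falls were smaller. CAV1, the caveolae scaffold, had a log2 fold change of -1.27 (8.31 ± 1.10 against 20.1 ± 0.657 CPM, adjusted p = 0.00104), LIX1 -1.26 (adjusted p = 0.00186) and the Golgi mannosidase MAN1A1 -0.79 (adjusted p = 0.00186). These genes kept their call in every alternative and with any 1 library left out. The other falls lost it with some libraries left out. The kinase adaptor CABLES1 fell by 0.90 on the log2 scale (adjusted p = 0.00961, range over alternatives 2.91e-09 to 0.0669), with 0.0642, 0.0669 and 0.0647 without DMSO 1, 2 and 3. The gluconeogenic enzyme FBP1 fell by 0.99 (adjusted p = 0.0149, range 2.14e-10 to 0.0945), with 0.0623 without bryostatin 3 and 0.0789, 0.0868 and 0.0945 without DMSO 1, 2 and 3. The actin-binding profilin PFN2 fell by 0.91 (adjusted p = 0.0296, range 3.58e-12 to 0.146), with 0.0745 and 0.110 without bryostatin 2 and 3 and 0.126, 0.136 and 0.146 without DMSO 1, 2 and 3. The membrane protein gene TMEM100 fell by 0.79 (adjusted p = 0.00661, range 7.05e-06 to 0.0596), with 0.0596 and 0.0563 without DMSO 1 and 2.

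**Figure D1:**
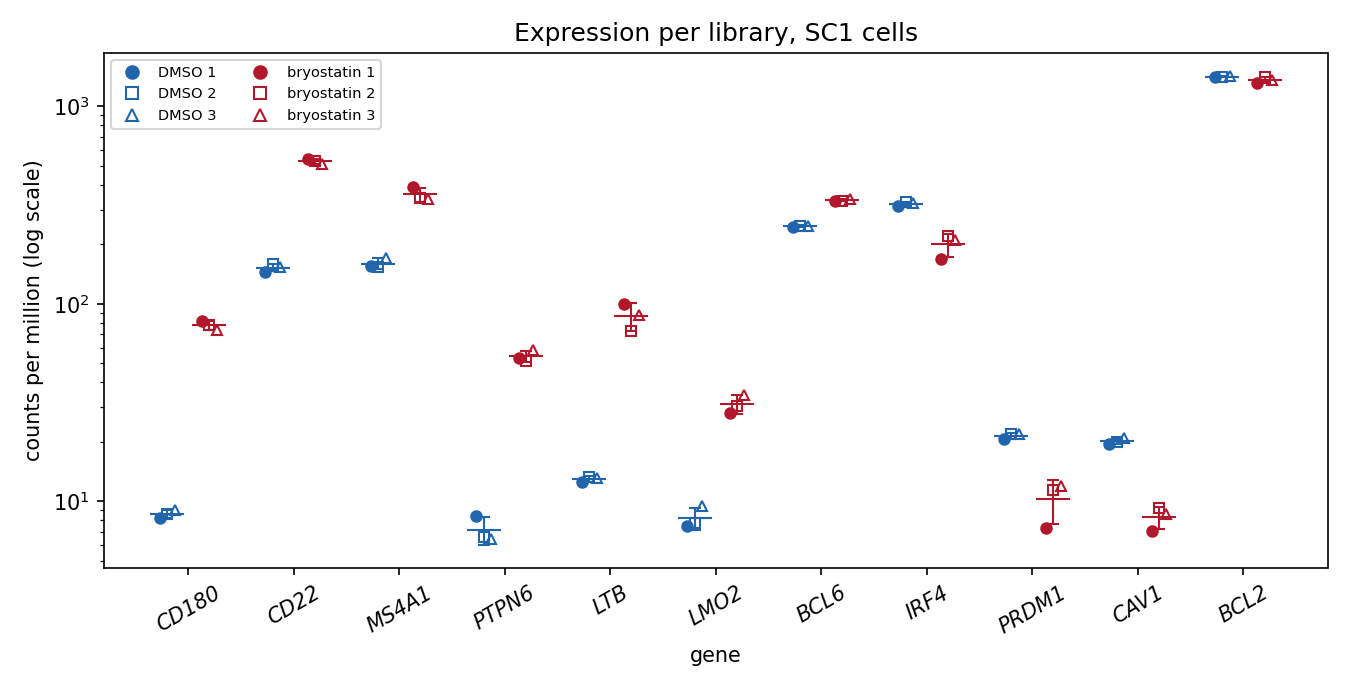
CPM of 11 named genes on a log axis, 1 point per library, with bars for the group mean ± SD (n = 3 libraries in each group). CD180 lay at 77.9 ± 3.79 CPM with bryostatin and 8.65 ± 0.391 CPM with DMSO, while BCL2 lay at 1360 ± 48.2 and 1411 ± 3.94 CPM.

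Surface antigens of B cells rose more often than they fell. Of 24 tested, 13 rose, 2 fell and 9 did not pass (16 and 4 adjusted over the list alone), with a median log2 fold change of 0.60. CD180 (chromosome 5, 67179613 to 67196799, GRCh38) had the lowest p, with a log2 fold change of 3.17 ± 0.09 (edgeR adjusted p = 4.03e-06). CD22 (chromosome 19, 35329187 to 35347361) rose by 1.79 ± 0.06 to 526 ± 15.1 from 152 ± 6.62 CPM (adjusted p = 9.41e-06). MS4A1 (chromosome 11, 60455847 to 60470752), which encodes CD20, the target of rituximab, rose by 1.16 to 358 ± 29 from 160 ± 9.78 CPM (adjusted p = 2.34e-04). CD79B, a signal-transducing chain of the B-cell receptor, had a log2 fold change of 0.23 (adjusted p = 0.125, range over alternatives 0.00280 to 0.429, with 0.00371 without bryostatin 1). Chosen after their values were seen, the complement receptor CR2 rose by 4.10 from near zero (2.53 ± 0.470 against 0.141 ± 0.122 CPM, adjusted p = 0.00455) and TNFRSF13B, a receptor for survival factors of the B lineage, fell by 1.08 (adjusted p = 0.00554). The list was shifted against other genes (camera adjusted p = 6.40e-09, but adjusted p = 0.121 with an estimated correlation). Without bryostatin 1, 17 of 25 rose and 6 fell, and without any other single library 1 fell.

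Some B-cell receptor signalling genes rose too, with 8 of 30 rising, 1 falling and 21 not passing (13 and 1 adjusted over the list alone) and a median log2 fold change of 0.18. The list median lay 0.04 above the DMSO mean in bryostatin 1, against 0.19 and 0.23 in bryostatin 2 and 3. PTPN6 (chromosome 12, 6946577 to 6961316), which dephosphorylates receptor signalling proteins, rose by 2.92 ± 0.13 to 54.1 ± 3.59 from 7.16 ± 1.13 CPM (edgeR adjusted p = 2.37e-05). The camera test gave adjusted p = 7.59e-06, and adjusted p = 0.126 with an estimated correlation. Leaving out bryostatin 1 gave 20 rising, while leaving out DMSO 1, 2 or 3 gave 4, 4 and 3, and bryostatin 3 gave 5. The TPM values gave 4, and quality weights 20.

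The germinal centre genes that passed rose, and the plasma-cell genes that passed fell. Of 23 germinal centre genes, 10 rose and 13 did not pass (14 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.50. LMO2, a transcriptional co-factor used as a germinal centre marker, rose by 1.91 to 31.0 ± 3.38 from 8.23 ± 1.07 CPM (edgeR adjusted p = 2.34e-04), and the DNA glycosylase NEIL1 rose by 1.68 (adjusted p = 0.00146). BCL6, the repressor that maintains the germinal centre state, rose by 0.43 to 334 ± 4.41 from 247 ± 2.38 CPM (adjusted p = 0.00455, range over alternatives 3.41e-08 to 0.0604), with 0.0570 without DMSO 1 and 0.0604 on the TPM values. Of 20 plasma-cell genes, 6 fell and 14 did not pass (11 lower adjusted over the list alone), with a median of -0.32. PRDM1 (chromosome 6, 105992690 to 106109938), which encodes Blimp-1, the repressor that drives plasma-cell differentiation, fell by 1.07 on the log2 scale to 10.2 ± 2.54 from 21.5 ± 0.741 CPM (adjusted p = 0.0123, range 3.53e-07 to 0.0846), with 0.0655, 0.0808 and 0.0846 without DMSO 1, 2 and 3. IRF4, a transcription factor of activated B cells and plasma cells, fell by 0.68 to 200 ± 27.0 from 321 ± 7.34 CPM (adjusted p = 0.00798, range 1.79e-09 to 0.0623), with 0.0505, 0.0605 and 0.0623 without DMSO 1, 2 and 3. CAV1 is also on this list. Camera gave adjusted p = 6.40e-09 for germinal centre genes and 3.35e-05 for plasma-cell genes, but adjusted p = 0.0699 and 0.121 with an estimated correlation. Without bryostatin 1, 17 germinal centre genes rose and 2 fell, and 13 of 21 plasma-cell genes fell. On the TPM values 6 germinal centre genes rose. Without DMSO 1, 2 or 3 the germinal centre count was 6, 7 and 6, the plasma-cell count was 1 each time, and without bryostatin 3 it was 3.

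Few transcription factors of B-cell identity passed, with 3 of 21 rising and 18 not passing (4 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.562). SPI1, the ETS factor PU.1, rose by 0.66 on the log2 scale (edgeR adjusted p = 0.00530, range over alternatives 9.45e-08 to 0.0554), with 0.0554 and 0.0517 without DMSO 1 and 3. FOXO1, a forkhead factor restrained by AKT, rose by 0.36 (adjusted p = 0.0224, range 4.95e-05 to 0.172). Its adjusted p was 0.0745 and 0.0696 without bryostatin 2 and 3, 0.161, 0.132 and 0.146 without DMSO 1, 2 and 3, and 0.172 on the TPM values. Without bryostatin 1, 10 of the list rose and 3 fell; without bryostatin 2, bryostatin 3 or DMSO 2 the count was 1, and without DMSO 1 or DMSO 3 it was 0, against 5 higher and 2 lower at an unadjusted p under 0.05 in all 6 libraries, 3 and 1 by DESeq2, and 1 higher on the TPM values or with the replicate block.

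Some NF-kB target, cytokine and activation genes rose, among them LTB, TNF and CD40. Of 31 NF-kB targets, 10 rose, 1 fell and 20 did not pass (16 and 1 adjusted over the list alone), with a median log2 fold change of 0.28 (0.11 in bryostatin 1 against 0.34 and 0.33 in bryostatin 2 and 3). LTB rose by 2.74 to 86.8 ± 13.6 from 13 ± 0.438 CPM (edgeR adjusted p = 3.75e-05), the co-stimulatory receptor CD40 by 1.18 (adjusted p = 2.64e-04), the lymphotoxin LTA by 2.47 (adjusted p = 7.43e-04) and the cytokine TNF by 2.22 to 7.90 ± 1.30 from 1.69 ± 0.185 CPM (adjusted p = 7.60e-04). Of 10 cytokine and chemokine genes, 4 rose and 6 did not pass (4 adjusted over the list alone), with a median of 0.41 (0.62 without bryostatin 3, 0.23 and 0.21 without DMSO 1 and 3, and 0.24 by DESeq2). Of 23 activation and co-stimulation genes, 9 rose and 14 did not pass (16 adjusted over the list alone), with a median of 0.65. CD48, an adhesion and co-stimulatory ligand, rose by 1.58 (adjusted p = 8.27e-04). Of 19 migration and adhesion genes, 7 rose and 12 did not pass (7 adjusted over the list alone), with a median of 0.18 (0.33 and 0.11 without bryostatin 1 and 2). ITGB2, the common beta chain of leukocyte integrins, rose by 4.36 from a low level (6.30 ± 0.781 against 0.301 ± 0.126 CPM, adjusted p = 1.99e-04), and RGS1, which dampens chemokine receptor signalling, by 1.68 (adjusted p = 0.00184). The camera adjusted p for NF-kB targets, cytokines, activation and migration was 4.89e-07, 1.45e-04, 2.95e-09 and 5.17e-04, but adjusted p = 0.233, 0.121, 0.121 and 0.126 with an estimated correlation. Without bryostatin 1 the risers numbered 21, 5, 15 and 11. Activation genes numbered 5 without any 1 DMSO library and 6 without bryostatin 3, and migration genes 4 without DMSO 1. Without bryostatin 1, 2 NF-kB targets and 1 migration gene fell.

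Some antigen presentation and interferon-stimulated genes rose. Of 15 MHC class I genes, 3 rose and 12 did not pass (4 adjusted over the list alone), and of 18 MHC class II genes, 5 rose and 13 did not pass (14 adjusted over the list alone), with median log2 fold changes of 0.21 and 0.31 (class II 0.21 without bryostatin 1, with 0.47 above the DMSO mean in that library against 0.25 and 0.19 in bryostatin 2 and 3). HLA-E, a non-classical class I molecule, rose by 1.08 to 177 ± 4.53 from 83.5 ± 2.26 CPM (edgeR adjusted p = 1.11e-04). IFI30, a lysosomal thiol reductase of antigen processing, rose by 1.73 (adjusted p = 1.21e-04) and HLA-DQA1, a class II alpha chain, by 0.83 (adjusted p = 8.27e-04). HLA genes share reads with near-identical relatives, so their single values are uncertain. The peptide-loading factor TAPBP rose by 0.69 (adjusted p = 0.00533, range over alternatives 9.14e-10 to 0.0999), with 0.0517 without DMSO 1 and 0.0999 on the TPM values. Of 30 interferon-stimulated genes, 10 rose and 20 did not pass (22 adjusted over the list alone), with a median of 1.01. Of these genes 6 rose with library size alone, 5 by limma-voom, 2 on the TPM values and 24 with quality weights. IFITM2, an antiviral membrane protein, rose by 2.32 to 14.2 ± 3.78 from 2.84 ± 0.405 CPM (adjusted p = 0.00119). Its near relative IFITM1, with which it may share reads, rose by 1.93 to 27.8 ± 10.6 from 7.32 ± 0.187 CPM (adjusted p = 0.00813, range 1.80e-13 to 0.0669), with 0.0563, 0.0669 and 0.0647 without DMSO 1, 2 and 3. In bryostatin 1 the median interferon gene lay 0.33 above the DMSO mean, against 1.21 and 1.11 in bryostatin 2 and 3. Camera gave adjusted p = 4.44e-04, 1.13e-08 and 1.31e-08 for class I, class II and interferon genes, but adjusted p = 0.240, 0.240 and 0.286 with an estimated correlation. Without bryostatin 1 the risers numbered 10, 14 and 26 (of 32 interferon genes). Interferon risers numbered 3 and 3 without bryostatin 2 and 3 and 1, 2 and 1 without DMSO 1, 2 and 3. Class I risers numbered 1 without DMSO 1 and class II risers 3. With the length and GC offset class I, class II and interferon risers numbered 4, 12 and 12.

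**Figure D2:**
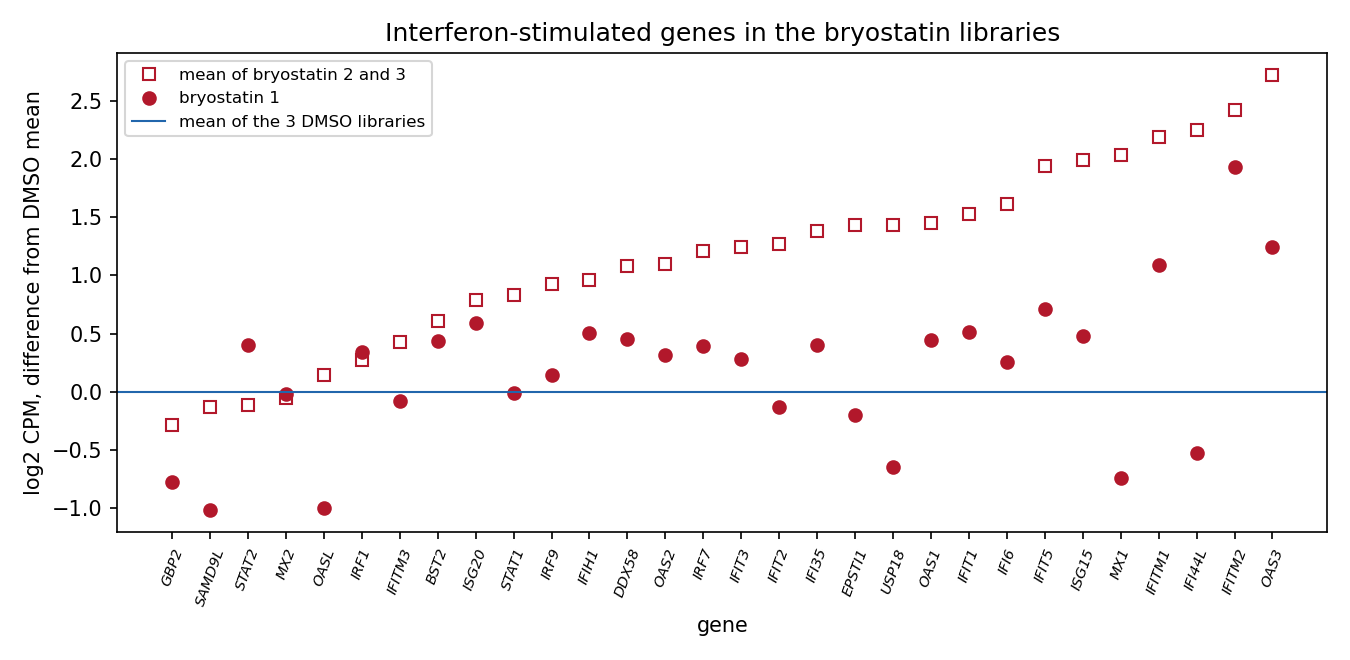
Log2 difference from the DMSO mean (y axis) for the 30 interferon-stimulated genes tested (x axis), with a horizontal line at the DMSO mean. For each gene a filled circle marks bryostatin 1 and an open square the mean of bryostatin 2 and 3. For 27 of the 30 genes the value in bryostatin 1 was lower than that mean.

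PKC genes and the kinase cascades around them showed few changes. Of 9 PKC and PKD genes, 1 rose and 8 did not pass (2 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.910), with a median log2 fold change of -0.04 (-0.14, -0.06, 0.02 and -0.07 without bryostatin 1, bryostatin 2, bryostatin 3 and DMSO 2) and a mean of 0.04. PRKD2, a kinase activated downstream of PKC, rose by 0.74 (edgeR adjusted p = 0.00787, range over alternatives 8.54e-10 to 0.0657), with 0.0642 and 0.0657 without DMSO 1 and 3 and 0.0556 on the TPM values. The log2 fold change was 0.33 for the calcium-independent isozyme PRKCD (adjusted p = 0.0520), -0.47 for the conventional isozyme PRKCA (0.0899), -0.24 for PRKD3 (0.166), -0.37 for PRKCE (0.258) and -0.04 for PRKCB (0.928). Without bryostatin 1 PRKCE had -0.20, and PRKCB had -0.07, -0.07, 0.02, 0.00 and -0.08 without bryostatin 1, 2 and 3 and DMSO 1 and 2. Without bryostatin 1 the adjusted p values of PRKCD, PRKCA, PRKD3, PRKCE and PRKCB were 1.57e-04, 2.68e-04, 0.0128, 0.0416 and 0.796, and the list had 2 rising and 4 falling. The highest adjusted p over the alternatives was 0.296, 0.305, 0.444, 0.545 and 0.998, and the lowest was that without bryostatin 1 except for PRKCE and PRKCB, at 0.0394 and 0.700 with quality weights. Of 18 diacylglycerol-regulated and MAPK upstream genes, 1 rose and 17 did not pass (1 adjusted over the list alone, camera adjusted p = 0.586). That was RASGRP1, a diacylglycerol-regulated activator of RAS, at 1.47 (adjusted p = 0.00253). The kinase gene DGKA, which removes diacylglycerol, had 0.47 (adjusted p = 0.143, and 0.0272 without bryostatin 1 at a change of 0.28, range over alternatives 0.0243 to 0.416), and without that library 7 of the list rose and 2 fell. Of 27 immediate-early and ERK output genes, 5 rose, 1 fell and 21 did not pass (6 and 4 adjusted over the list alone, camera adjusted p = 0.376). SPRED2, an inhibitor of the RAS pathway, rose by 1.31 (adjusted p = 8.27e-04). The orphan nuclear receptor NR4A3 fell by 2.42 on the log2 scale to 1.26 ± 0.452 from 6.83 ± 0.793 CPM (adjusted p = 0.00201). ETV4, an ETS factor chosen after its values were seen, rose by 3.62 from a low level (1.81 ± 0.271 against 0.142 ± 0.113 CPM, adjusted p = 0.00392). Without bryostatin 1, 9 rose and 4 fell, and 3 rose without bryostatin 3 or any 1 DMSO library, on the TPM values or with the replicate block, and 4 fell by DESeq2.

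Few survival genes passed the test. Of 17 BCL2 family genes, 1 rose and 16 did not pass (2 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.710), with a median log2 fold change of -0.04 (0.00 without bryostatin 2, bryostatin 3 or DMSO 2 and -0.03 without DMSO 3) and a mean of 0.10. BIK, a pro-apoptotic BH3-only protein, rose by 1.27 to 10.8 ± 1.52 from 4.46 ± 0.585 CPM (edgeR adjusted p = 0.00471). BCL2 lay at 1360 ± 48.2 against 1411 ± 3.94 CPM, with a log2 fold change of -0.05 (adjusted p = 0.694, and -0.03 and -0.08 without bryostatin 1 and 2), and MCL1 at -0.04 (0.828, and 0.04, -0.10 and -0.09 without bryostatin 1, 2 and 3), both anti-apoptotic. The pro-apoptotic genes HRK, PMAIP1 and BCL2L11 had 0.44, -0.21 and -0.22 (adjusted p = 0.104, 0.105 and 0.117, and 0.0242, 5.00e-04 and 5.15e-04 without bryostatin 1). Over the alternatives these ranged from 0.0127 to 0.367, 5.00e-04 to 0.392 and 5.15e-04 to 0.392. Without bryostatin 1, 3 of the family rose and 3 fell. Of 27 p53 targets and CDK inhibitors, 1 rose and 26 did not pass (3 adjusted over the list alone, camera adjusted p = 0.178). It was the death receptor FAS, at 1.45 (adjusted p = 0.00754, range over alternatives 7.80e-07 to 0.0617), with 0.0617 without DMSO 2. The stress-response gene SESN2 had 0.64 (adjusted p = 0.0520, range 6.35e-05 to 0.230, with 6.35e-05 without bryostatin 1 and 0.0476 without bryostatin 3). Without bryostatin 1, 8 of the p53 list rose and 4 fell, and 2 rose without bryostatin 3.

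Few growth and cell-cycle genes passed. Of 33 ribosome biogenesis and MYC target genes, 2 fell and 31 did not pass (8 lower adjusted over the list alone), with a median log2 fold change of -0.21 (camera adjusted p = 2.81e-07, but adjusted p = 0.121 with an estimated correlation). The list median was -0.32 in bryostatin 1 against -0.16 and -0.12 in bryostatin 2 and 3. RRP9, a ribosomal RNA processing factor, fell by 0.63 to 64.5 ± 2.67 from 100 ± 4.17 CPM (edgeR adjusted p = 0.00288). ODC1, the first enzyme of polyamine synthesis, fell by 0.37 (adjusted p = 0.0312, range over alternatives 1.46e-08 to 0.170). Its adjusted p was 0.104 and 0.122 without bryostatin 2 and 3 and 0.170, 0.165 and 0.158 without DMSO 1, 2 and 3. The transcription factor MYC had -0.18 (adjusted p = 0.283), and -0.11 without bryostatin 1. Of 31 S-phase genes, 2 fell and 29 did not pass (3 adjusted over the list alone, camera adjusted p = 0.107). The exonuclease EXO1 fell by 0.35 (adjusted p = 0.0243, range 3.48e-05 to 0.151, with 0.0601 on the TPM values) and the ribonucleotide reductase subunit RRM2 by 0.30 (0.0225, range 4.22e-06 to 0.153). Without bryostatin 2, bryostatin 3, DMSO 1, DMSO 2 and DMSO 3 the adjusted p of EXO1 was 0.0559, 0.0739, 0.124, 0.149 and 0.151, and that of RRM2 0.0834, 0.0773, 0.153, 0.140 and 0.148. Of 36 G2 and M phase genes, 0 passed in edgeR, with 5 higher and 1 lower at an unadjusted p under 0.05, 1 higher by DESeq2 and 0 adjusted over the list alone. The kinetochore gene NUF2 had 0.31 (adjusted p = 0.0568) and the spindle gene NUSAP1 0.21 (0.112), and 7.61e-04 and 0.00316 without bryostatin 1, the lowest over the alternatives, which reached 0.272 and 0.385. The median of that list was 0.10 (camera adjusted p = 0.0152, but adjusted p = 0.240 with an estimated correlation). By DESeq2 6 ribosome biogenesis genes fell. Without bryostatin 1, 19 ribosome biogenesis genes fell, 1 S-phase gene rose and 6 fell, and 10 G2 and M genes rose and 2 fell. Without any other single library, 1 ribosome biogenesis gene fell and 0 S-phase genes did, against 6 lower S-phase genes at an unadjusted p under 0.05 in all 6 libraries and 3 by DESeq2.

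Metabolic and protein-folding lists held few calls. Of 24 cholesterol synthesis genes, 1 rose and 23 did not pass (3 adjusted over the list alone), with a median log2 fold change of 0.27 (camera adjusted p = 1.34e-04, but adjusted p = 0.126 with an estimated correlation). Bryostatin 1, 2 and 3 lay at 0.12, 0.33 and 0.28 above the DMSO mean. The gene that rose was IDI1, an isomerase of isoprenoid synthesis, at 0.36 (edgeR adjusted p = 0.0256, range over alternatives 2.23e-06 to 0.226). Its adjusted p was 0.0734, 0.112, 0.166, 0.154 and 0.122 without bryostatin 2, bryostatin 3, DMSO 1, DMSO 2 and DMSO 3, 0.0606 with library size alone and 0.226 on the TPM values. In the fits without those 5 libraries 0 of the list rose, against 10 at an unadjusted p under 0.05 in all 6 libraries and 4 by DESeq2. FDFT1, which makes squalene, had 0.35 (adjusted p = 0.0520, and 8.39e-05 without bryostatin 1, range 8.39e-05 to 0.244), and 15 of the list rose without that library. Of 22 glycolysis genes, 3 rose and 19 did not pass (4 adjusted over the list alone, camera adjusted p = 0.361). The phosphofructokinase PFKL rose by 0.55 (adjusted p = 0.00851, range 8.08e-07 to 0.0698), with 0.0698 and 0.0688 without DMSO 1 and 3. The lactate exporter SLC16A3 rose by 1.63 (adjusted p = 0.0439, range 0.00166 to 0.211), with 0.0828 without bryostatin 3, 0.141, 0.182 and 0.211 without DMSO 1, 2 and 3 and 0.0604 by limma-voom. Without bryostatin 1, 4 of the list rose and 5 fell, and without bryostatin 3, DMSO 1, DMSO 2 and DMSO 3 1, 0, 1 and 0 rose, against 4 at an unadjusted p under 0.05 in all 6 libraries and 4 by DESeq2. Of 25 unfolded protein response genes, 1 rose, 1 fell and 23 did not pass (1 and 1 adjusted over the list alone, camera adjusted p = 0.672). The disulfide isomerase PDIA3 rose by 0.39 (adjusted p = 0.0114, range 1.20e-06 to 0.105), with 0.105, 0.0889 and 0.0864 without DMSO 1, 2 and 3 and 0.0804 on the TPM values. The endoplasmic reticulum chaperone HSP90B1 fell by 0.45 (adjusted p = 0.0454, range 2.76e-06 to 0.195), with 0.113 without bryostatin 3 and 0.184, 0.195 and 0.191 without DMSO 1, 2 and 3, 0.0541 with library size alone and 0.0896 on the TPM values. Without bryostatin 1, 3 of that list rose and 4 fell. Of 28 autophagy and lysosome genes, 1 rose and 27 did not pass (1 adjusted over the list alone, camera adjusted p = 0.178, and 0.0309 without bryostatin 3, range 0.0309 to 0.624). The lysosomal protease CTSZ rose by 0.46 (adjusted p = 0.0104, range 2.02e-06 to 0.0925), with 0.0581 without bryostatin 3 and 0.0925, 0.0750 and 0.0918 without DMSO 1, 2 and 3 and 0.0738 on the TPM values. The lysosomal transcription factor TFEB had 0.37 (adjusted p = 0.0902, and 5.35e-04 without bryostatin 1, range 2.56e-04 to 0.365), and 4 of the list rose and 1 fell without that library.

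**Figure D3:**
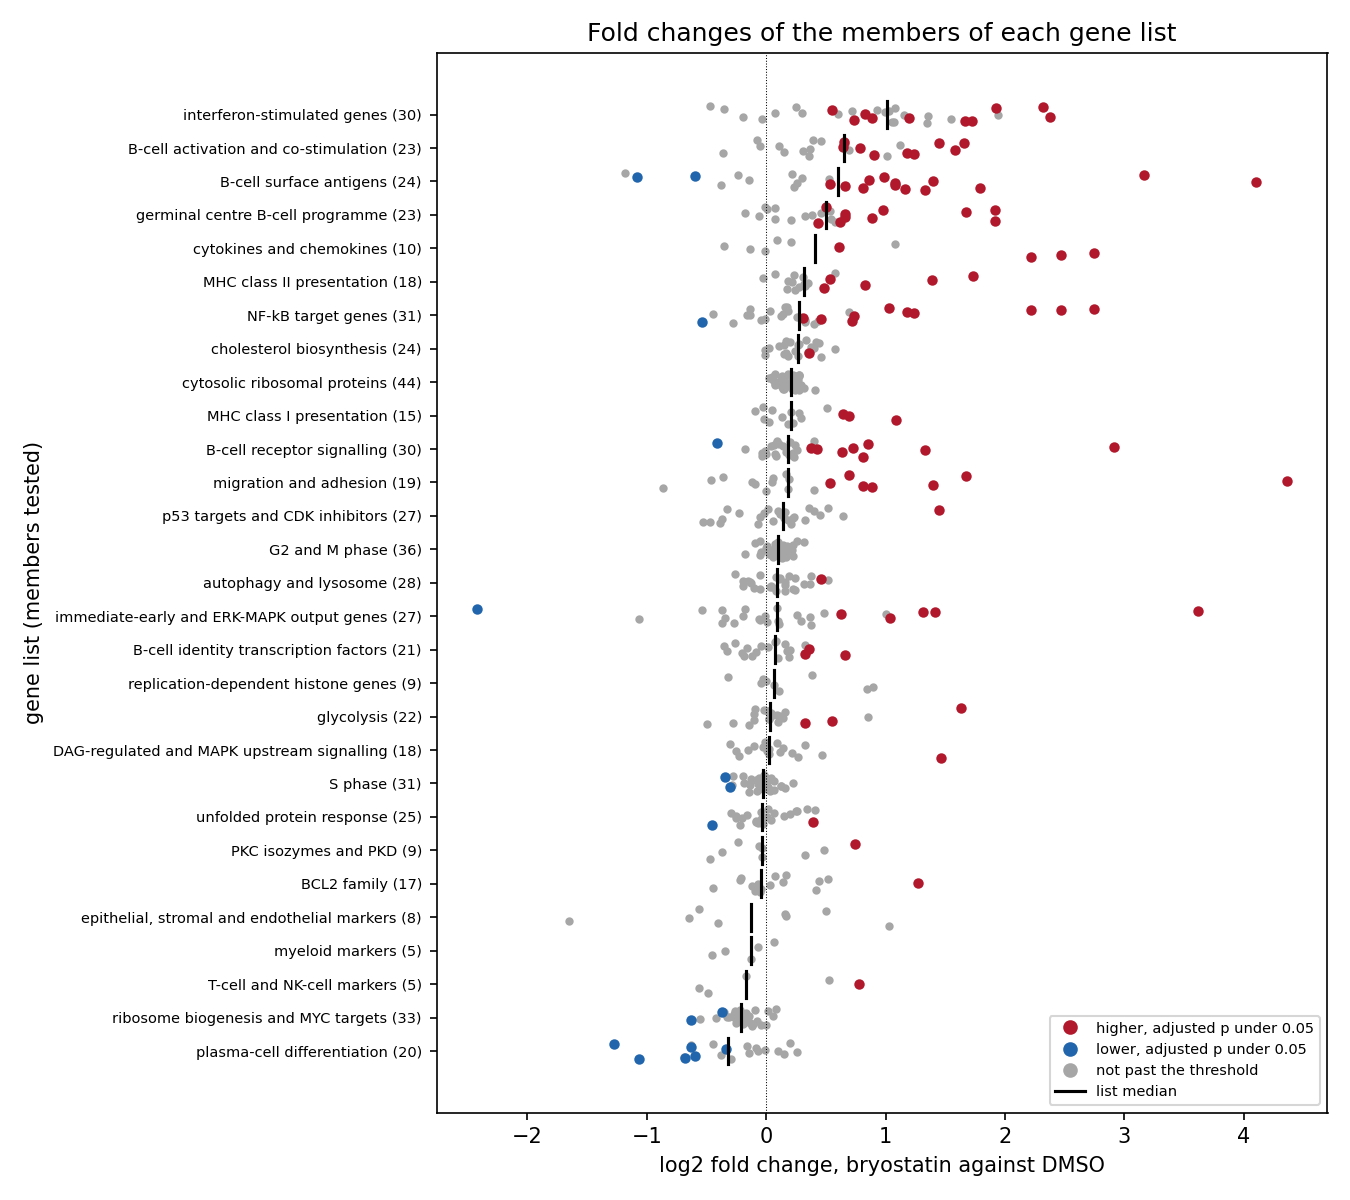
Log2 fold change (bryostatin over DMSO) of each tested member of each gene list, 1 point per gene, red for genes called higher, blue for genes called lower and grey for the rest, with a black line at the list median. The median was 1.01 for interferon-stimulated genes, 0.60 for B-cell surface antigens and -0.32 for plasma-cell genes.

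Markers of other cell types stayed low. Summed T-cell and NK-cell markers reached 36.9 to 43.3 CPM with bryostatin and 27.9 to 30.2 CPM with DMSO, most of it from LCK, a SRC-family kinase that B cells also express. LCK rose by 0.78 on the log2 scale and was the 1 of 5 tested members to pass (4 did not, 1 adjusted over the list alone, camera adjusted p = 0.844). Its edgeR adjusted p was 0.00806 (range over alternatives 1.64e-06 to 0.0675), with 0.0554, 0.0675 and 0.0671 without DMSO 1, 2 and 3. The interleukin receptor IL7R had -0.56 (adjusted p = 0.182, and 0.0414 with quality weights, range 0.0414 to 0.431). Myeloid markers summed to 22.6 to 34.3 CPM with bryostatin and 27.7 to 41.0 CPM with DMSO, and epithelial, stromal and endothelial markers to 8.76 to 15 and 12.1 to 16.7 CPM. Of 5 myeloid and 8 epithelial, stromal and endothelial markers tested, 0 passed in edgeR, with 0 and 1 at an unadjusted p under 0.05, 0 and 1 by DESeq2, and 0 and 1 adjusted over the list alone (camera adjusted p = 0.371 and 0.451). The calprotectin genes S100A8 and S100A9 had -0.46 and -0.35 (adjusted p = 0.397 and 0.542, with changes of -0.25 and -0.10 without bryostatin 1 and -0.26 and -0.21 without DMSO 1, and S100A9 at -0.55 and -0.53 without bryostatin 3 and DMSO 2), the collagen COL1A1 -1.66 (0.0778, and 0.0124 without bryostatin 1, range 0.0124 to 0.288) and the endothelial adhesion molecule PECAM1 -0.56 (0.303, and 0.0309 with quality weights, range 0.0309 to 0.560).

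Composition differed most in bryostatin 1, in which short transcripts were over-represented. Against the other 2 bryostatin libraries, its median log2 difference was 0.28 in the shortest of 4 length bins and -0.29 in the longest, while DMSO libraries stayed between -0.04 and 0.06. Bryostatin 1 also had the fewest genes with a value over 0, at 13930 against 14123 to 14357 in the other libraries. Its mean Pearson correlation with its group over genes was 0.981, against 0.988 for bryostatin 2 and 3 and 0.994 for each DMSO library. The 0.988 includes the correlation with bryostatin 1, and between bryostatin 2 and 3 it was 0.994. The 10 most abundant genes took 6.67% ± 0.630 of counts with bryostatin and 5.94% ± 0.0673 with DMSO (SD, n = 3 each), a difference of 0.725 percentage points (exact 2-sided permutation p = 0.1, the smallest 3 against 3 can give), and of 0.362 without bryostatin 1. Of 44 cytosolic ribosomal protein genes, which are short, 0 passed in edgeR, with 14 higher at an unadjusted p under 0.05, 2 higher by DESeq2, 3 on the TPM values and 0 adjusted over the list alone. With the length and GC offset 13 of these genes were higher and 0 lower, at a list median log2 fold change of 0.18. Their median log2 difference from the DMSO mean was 0.43 in bryostatin 1, 0.03 in bryostatin 2 and 0.09 in bryostatin 3. RPL3 and RPL22 had 0.41 and 0.29 (adjusted p = 0.0615 and 0.0836, and 7.83e-06 and 3.29e-04 without bryostatin 1, the lowest over the alternatives, which reached 0.278 and 0.318). The list median was 0.21, and 0.07 without bryostatin 1 (camera adjusted p = 1.75e-05, but adjusted p = 0.689 with an estimated correlation and 0.0640 without bryostatin 1, range over the alternatives 1.05e-07 to 0.689), and 13 rose and 1 fell without that library. Of 9 replication-dependent histone genes, whose transcripts largely lack poly(A) tails, 0 passed in edgeR, 0 at an unadjusted p under 0.05, 0 by DESeq2 and 0 adjusted over the list alone (camera adjusted p = 0.734), with H1-4 at 0.85 (0.353, and 0.56, 0.54 and 1.34 without bryostatin 3, DMSO 2 and DMSO 3) and H1-5 at 0.89 (0.514), but at -0.31 without bryostatin 3.

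**Figure D4:**
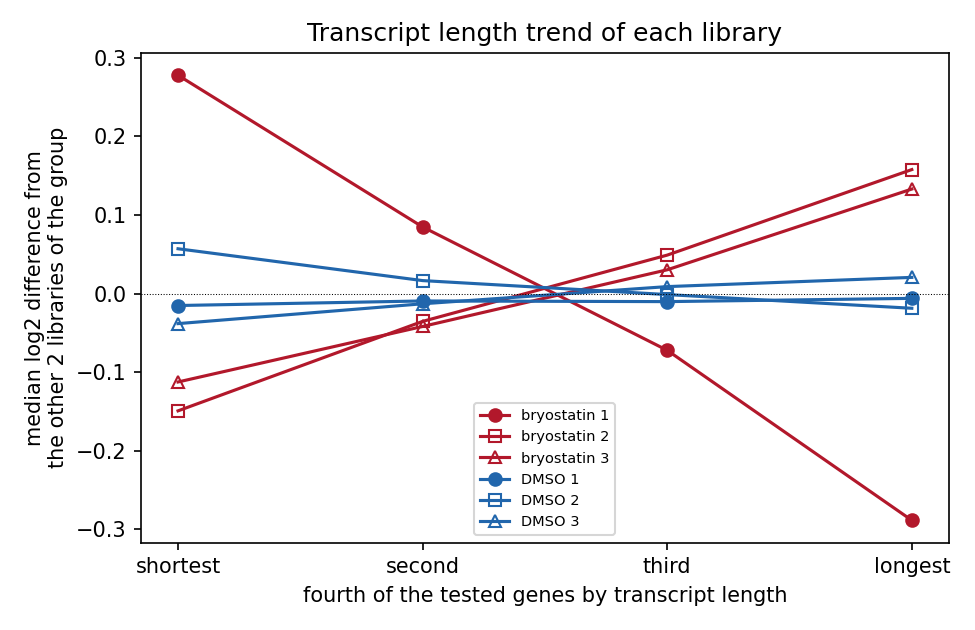
Median log2 difference of each library from the other 2 of its group, in 4 equal bins of the tested genes ordered by transcript length, 1 line per library. Bryostatin 1 runs from 0.28 in the shortest bin to -0.29 in the longest, while bryostatin 2 and 3 run the other way by up to 0.16. Bryostatin 1 is among the libraries that bryostatin 2 and 3 are compared with.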

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

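The alternative settings chosen only after the data were seen were the quality weights and the length and GC offset. Of 529 changed genes, 432 higher, 97 lower and 146 over 2-fold, the counts stayed within 1.5 times with RLE or upper quartile factors, library size alone, no filter, a mean count of at least 10 and limma-voom, which shared 523, 527, 460, 502, 528 and 497 of the calls with the same direction. DESeq2 called 865, 236 of them lower. The TPM values gave 266 higher, 195 lower and 64 over 2-fold. Quality weights gave 3040, with 1609 higher, 1431 lower and 234 over 2-fold, and the length and GC offset 1222, with 782 higher and 440 lower. For each of these the cause was not tested. With the replicate block 338 changed, 284 higher and 54 lower, and the cause was not tested. Correlations of same-numbered libraries' deviations from their group means were -0.21, -0.17 and 0.03, and no bryostatin library correlated best with its own number. Deviations within a group of 3 depend on each other, so these values cannot exclude a culture or day shared by number. The block changed no list call. Leaving out 1 library at a time gave 138 (DMSO 1) to 3183 (bryostatin 1) changed genes, 128 to 1632 higher, 10 to 1551 lower and 82 to 242 over 2-fold. Fewer samples enter each of these fits, but the rise without bryostatin 1 goes with a biological coefficient of variation of 0.0430 in place of 0.114. Camera called 15 lists and 14 to 16 with 1 library left out, ending the call of ribosomal proteins without bryostatin 1 and adding autophagy and lysosome without bryostatin 3. It called 0 with an estimated correlation, against 9 at an unadjusted p under 0.05 and 17 by fry, and the cause was not tested. By fry the diacylglycerol and MAPK, p53 and S-phase lists passed (adjusted p = 0.0264, 0.0262 and 0.00614) and ribosomal proteins did not (0.308). The difference in the 10 most abundant genes ranged from 0.362 to 0.909 percentage points. Of the 54 named genes that passed, 31 kept the call under every alternative, 42 under all but left-out libraries, and 23 lost it without at least 1 library, with no direction reversed. Of simulated 1.5-fold changes 58.2% were recovered, and 77.6% without bryostatin 1, where the fitted spread is smaller, so small changes can be missed. The simulation spread the variation alike over all libraries, unlike the data, so these shares are not the power of the real test. Depth itself was not varied. On log2(TPM + 1) the medians of NF-kB targets, receptor signalling, activation, class I, interferon, migration, cholesterol, G2 and M phase and ribosomal protein genes were 0.18, 0.06, 0.41, 0.12, 0.56, 0.07, 0.12, 0.00 and 0.11, and the changes of ITGB2, NR4A3, RASGRP1, SLC16A3, CR2, ETV4 and TLR6 were 1.95, -1.14, 0.79, 0.76, 0.90, 1.08 and 0.57.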

Other observations

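The genes of Toll-like receptors and the NADPH oxidase and HHEX were chosen after the result was seen. So were the tests on bryostatin 1, on weaker treatment, on dilution and on length or bryostatin 1 in the germinal centre pattern. The splits were not. The predictions on scaling and on length in the interferon genes were written before their test values, but for patterns already seen. Some Toll-like receptor transcripts rose. Of 14 Toll-like receptor and partner genes, 6 rose, CD180 among them, and 8 did not pass (7 rose without bryostatin 1), and the list was not tested against other genes. TLR1, a receptor for bacterial lipopeptides, rose by 1.58 on the log2 scale to 33.9 ± 4.21 from 11.3 ± 0.644 CPM (SD, n = 3, edgeR adjusted p = 3.61e-04). TLR10, expressed by B cells, rose by 0.91 to 98.2 ± 19.3 from 52.2 ± 2.18 CPM (adjusted p = 0.0101, range over alternatives 5.74e-12 to 0.0803), with 0.0727, 0.0764 and 0.0650 without DMSO 1, 2 and 3 and 0.0803 on the TPM values. TLR6, a partner of other Toll-like receptors, rose by 0.91 (0.00833, range 8.87e-08 to 0.103), with 0.0655, 0.0653 and 0.0647 without DMSO 1, 2 and 3 and 0.103 on the TPM values. LY86, the secreted partner of CD180, rose by 0.68 (0.0105, range 7.06e-06 to 0.0874), with 0.0851 and 0.0874 without DMSO 1 and 3. UNC93B1, which carries nucleic acid-sensing receptors to endosomes, rose by 0.83 (0.00813, range 6.14e-08 to 0.0671), with 0.0655 and 0.0671 without DMSO 1 and 3. The DNA sensor TLR9 and the adaptor MYD88 had -0.09 and 0.26 (adjusted p = 0.774 and 0.109).

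Some genes of the NADPH oxidase rose. Of 7 genes that include the proton channel HVCN1, 5 rose, HVCN1 among them (6 without bryostatin 1), and the list was not tested against other genes. RAC2, its GTPase, rose by 1.17 on the log2 scale to 213 ± 28.7 from 94.4 ± 4.24 CPM (edgeR adjusted p = 7.65e-04). NCF1, a cytosolic subunit, rose by 1.75 to 90.8 ± 8.0 from 27.0 ± 2.26 CPM (adjusted p = 1.11e-04), a value left uncertain by reads shared with near-identical pseudogenes. NCF4 rose by 1.01 (0.0292, range over alternatives 2.94e-04 to 0.161), with 0.0739 without bryostatin 3 and 0.149, 0.106 and 0.161 without DMSO 1, 2 and 3. CYBB, the catalytic subunit, rose by 0.62 (0.0445, range 4.40e-08 to 0.208), with 0.114 and 0.139 without bryostatin 2 and 3 and 0.189, 0.189 and 0.204 without DMSO 1, 2 and 3, 0.0749 with library size alone, 0.0558 by limma-voom and 0.208 on the TPM values. CYBA, a membrane subunit, had 0.35 (0.130). The homeobox factor HHEX rose, at 7.73 ± 1.43 against 2.93 ± 0.590 CPM (adjusted p = 0.00851, range 1.47e-06 to 0.0647), with 0.0629 and 0.0647 without DMSO 1 and 3.

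The germinal centre genes that passed rose and the plasma-cell genes that passed fell, with list medians 0.819 apart on the log2 scale. The medians stayed 0.824 apart with the length and GC offset and 0.759 apart without bryostatin 1, each above a bound of 0.4, so a length trend or bryostatin 1 is unlikely to be the whole source. The 0.820 with library size alone could not have moved, since a scaling shifts both lists alike. The medians kept their signs there, at 0.46 and -0.36, so the choice between these scalings set neither direction. That could hardly have come out otherwise, since library size alone moved the median of all genes only from -0.00139 to -0.0403. The signs are therefore no further support for the pattern. A hypothesis is that bryostatin may hold these cells nearer a germinal centre state, and PRDM1 and IRF4 protein over time would test it. The lists share no gene, and the calls of BCL6, PRDM1 and IRF4 were each lost without some DMSO library.

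Bryostatin 1 differed from the other 2 bryostatin libraries. Its total of 18.4 (in units of 1e+06 counts) lay within the 18.2 to 18.9 of the other libraries, so fewer reads were not the source. Over genes of at least 10 CPM on average, removing the length and GC trend lowered the SD of its log2 difference from the other 2 from 0.371 to 0.301. This was still above 0.0985, the SD between the other 2 after scaling for comparison with a mean of 2 libraries. The trend may thus be a part but not the whole. Genes changed over 2-fold in the other 2 responded in it at a median ratio of 0.779 (225 genes, quartiles 0.402 and 1.03, 95% bootstrap interval 0.684 to 0.843). This was just under a bound of 0.8 chosen after the data were seen, which the interval spans. Admixed untreated RNA could give such a ratio, but so could the choice of genes by their change in the other 2. The interval also treats the genes of 1 library as independent, so the ratio cannot decide on such RNA. Over 1611 genes of at least 10 CPM that were unchanged in those libraries its SD was 0.353, against 0.107 scaled in the same way. Admixed RNA alone would not give this, so a partial share of such RNA stays open beside a different culture or library preparation, which was not tested.

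Interferon-stimulated genes lay lower in bryostatin 1 than in its group, at 0.269 of the log2 change of the other 2, and 27 of 30 were lower. MX1, an antiviral GTPase chosen after its values were seen, lay at 16.7 CPM there against 114 and 115 in the other bryostatin libraries and 27.1, 30 and 26.9 with DMSO. The gap of the list median was 0.898 and became 1.09 after removal of the length and GC trend, above a bound of 0.4. Other genes raised over 2-fold had a median ratio of 0.870 (177 genes, interval 0.783 to 0.924 with genes taken as independent). Uniform dilution is thus unlikely to be the whole source. Other lists called higher had a median ratio of 1.02 but went both ways (12 lists, range 0.179 to 5.90), with receptor signalling, migration, cholesterol and NF-kB targets at 0.179, 0.296, 0.3984 and 0.4004 and class II and ribosomal proteins at 2.27 and 5.90, so weaker treatment stays open. A hypothesis is that the interferon genes may follow the culture rather than bryostatin in part, which libraries from cultures treated in parallel would test.

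Among the 10 splits of the 6 libraries into 3 and 3, 1 split, the real one, gave as many as 529 changed genes, 432 higher, 97 lower and 146 over 2-fold. The highest of the others was 0 for each count in edgeR, with 58 to 876 genes at an unadjusted p under 0.05 in those splits. Each of the other splits put treated and control libraries in the same group, so a treatment difference widens the spread within groups. Low counts there follow from that and do not measure chance. For gene lists the real split, 1 of 10, gave 15 and the others gave 2 to 12, so camera with the preset correlation also called lists where treated and control libraries were mixed. Those splits keep a part of the treatment difference, so 2 to 12 is not a rate of false calls. With 10 splits a share under 0.05 cannot be reached.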
